A study of Homo sapiens with 49 samples.

How the data were processed

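Gene expression was measured in 49 specimens of human ovarian epithelium, each on 1 Affymetrix HG-U133 Plus 2.0 array, a 1-colour array on which each transcript is read by a set of short probes (a probe set). Per the labels' protocols, epithelial cells were cut out of snap-frozen surgical tissue by laser capture microdissection, RNA was prepared with the Stratagene Absolutely RNA MicroPrep kit, and 25 ng was amplified over a pair of in vitro transcription rounds, primed from the poly(A) tail, before biotin labelling. How the captured regions were chosen beyond their epithelial origin is not given in the sources used here. Specimens were grouped by the labels alone: 6 of ovarian surface epithelium (HOSE), 8 serous borderline tumours (LMP, low malignant potential), 13 low-grade serous carcinomas (LGOSC) and 22 high-grade serous carcinomas (HGOSC). Replicate numbers follow the order of deposition and pair no specimens.

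The deposited values are linear probe set intensities, from a floor of 1 (73 values) to 61676.4, for 54675 probe sets. The array medians of these deposited intensities lay between 54.55 and 81.82. Background correction, summarisation and normalisation, and any scaling between arrays, are not given in the sources used here. The series' design text names dChip for the authors' comparison of LMP and LGOSC with HGOSC. The tests were run on log2(intensity + 16). The medians of these values spanned 0.471, under the limit of 0.5 set before the data were examined, so no further normalisation was applied. A log2 difference on this scale understates the change of dim genes. The number of arrays limits the precision of every comparison. The 99th percentile of intensity ranged from 2654 to 7907 between arrays. No array duplicated another, the highest correlation between 2 arrays being 0.975.

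Gene symbols came from the platform annotation, in which 41097 probe sets had 1 symbol, 1801 had several and 11777 had none. The Entrez identifiers of 41043 single-symbol probe sets matched the current gene table, and 0 symbols needed renaming. The 62 Affymetrix control probe sets, XIST and Y-linked genes were left out of the tests. A probe set was kept if it lay above its array's 40th percentile in at least 6 arrays, which left 33745. Each gene was represented by its named probe set with the highest mean, giving 17562 genes tested.

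Differences between groups were tested with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, with Benjamini-Hochberg adjustment. A gene passed at an adjusted p under 0.05 and an absolute log2 difference of at least 1. The comparison of HGOSC with LMP and LGOSC pooled, which is the one the series' design text states, was fitted on its 43 arrays. The other 5 comparisons came from 1 fit of 4 group means on all 49 arrays. No covariate entered these fits. Differences of AGR3 and AGR2 were also tested by 2-sided permutation, exact where a group had fewer than 10 specimens and enumeration was feasible and otherwise with 100000 resamples, adjusted over the 6 comparisons. All p-values are 2-sided.

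The lists of genes, 24 in all, were fixed before the data were examined, as were the groups, tests, thresholds, named genes and first set of alternative settings. The lists covered cell types (ciliated cell, serous and secretory epithelium, mesothelium and ovarian surface, ovarian stroma and steroidogenic cell, fibroblast and matrix, endothelium, T and NK cell, macrophage and monocyte, B and plasma cell, red blood cell). They also covered processes (mitosis, DNA replication and G1/S, homologous recombination repair, p53 targets, CDK inhibitors and the RB pathway, MAPK pathway output, oestrogen response, interferon response, MHC class II, immediate early response, epithelial junction and keratin, mesenchymal transcription and cytoskeleton, hypoxia and glycolysis, endoplasmic reticulum folding). Each was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, adjusted over the 24 lists. A list is called where the preset test gave an adjusted p under 0.05. Members were counted at an adjusted p under 0.05 over all genes tested, and also adjusted over the list alone. Of all 17562 genes, 4155 were higher and 5479 lower at that adjusted p in the pooled comparison. The counts were 4628 and 5775 for HGOSC against LGOSC, and 2718 and 1799 for LGOSC against LMP. Against HOSE they were 4596 and 2753 for LMP, 6914 and 4537 for LGOSC, and 3357 and 1849 for HGOSC. A member count near these shares is no sign of a list shift. A list's shift is the mean log2 difference of its measured members. The score of a list in a specimen is the mean of its members' z-scores.

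The genes named were AGR3 and its paralogue AGR2, and MKI67, CDKN2A, ESR1, PGR, PAX8, WT1 and MUC16, which are markers used for these tumours. To these were added, among genes past the threshold in which at least 90% of the specimens of 1 group lay beyond the other group's median, the 10 with the largest and the 10 with the smallest log2 difference in the pooled comparison, and the 5 and 5 of each other comparison. Symbols of uncharacterised loci and of immunoglobulin segments were passed over. For a list, up to 4 members with the largest absolute difference among those past the adjusted p were named, or the 2 with the smallest p where none passed.

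Array quality was read from 9 spike-in control probe sets and from the log2 ratio of 3′ to 5′ probe sets of ACTB and GAPDH, which rises where RNA is degraded or amplified products are short. Clustering the 9 spike-in probe sets placed the arrays in 3 sets (high, middle and low), chosen after the data were seen. Each comparison was refitted with the array set as a block, and within each set that held both groups. Fits within the middle set used its 31 arrays, and for the 5 comparisons other than the pooled one they held 4 group means.

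The other alternative settings were quantile normalisation, a shift of each array to a common 75th percentile, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile. The mean of all probe sets of a gene, leaving out probe sets that can match several transcripts (suffixes _x_at and _s_at), the 3′ to 5′ ratio as a covariate, array weights, eBayes with a trend and robust variances, and the fibroblast score as a covariate were also tried. Added after the data were seen was leaving out 8 HGOSC arrays whose log2 range from the 10th to the 90th percentile was at most 4.72, against at least 4.998 in the other 14. So were refits of the lists without each specimen. Planned were also leaving out each specimen in turn for the gene counts and AGR3, the adjusted p alone as the threshold, and a change in the groups that entered the fit. The limma and list steps were first tested on simulated data, with 100 of the 17562 genes changed per size. At a log2 change of 1.5, 94% were recovered for HGOSC against LMP and LGOSC, 94% for HGOSC against LGOSC, 81% for LGOSC against LMP, and 74%, 76% and 83% for LMP, LGOSC and HGOSC against HOSE, with 2 to 8 false calls. In the pooled comparison 1 list beside the planted one was also called. The simulated noise was independent between genes and held no array sets, so these rates do not cover the effect of either in the real arrays. Correlations, permutations and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Survival was not analysed here.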

Results

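Expression was profiled on arrays in laser-captured epithelium from 6 HOSE (normal ovarian surface epithelium), 8 LMP (serous borderline tumour), 13 LGOSC (low-grade serous carcinoma) and 22 HGOSC (high-grade serous carcinoma) specimens. The mean of the array medians was 71.7 intensity units in HOSE, 62.7 in LMP, 66.1 in LGOSC and 63.9 in HGOSC. The labels do not tie the captured specimens to patients or say that they came from separate donors, so the p-values measure only the spread between these specimens and are too small if some share a donor. The series is about AGR3, which encodes a secreted or endoplasmic reticulum protein of the disulfide isomerase family, and its relation to tumour differentiation.

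AGR3 was high in borderline tumours, intermediate and variable in low-grade carcinomas, and low in high-grade carcinomas and in normal surface epithelium. Its mean log2 intensity was 10.45 ± 0.51 (SD, n = 8) in LMP, 7.83 ± 1.87 (n = 13) in LGOSC, 5.92 ± 1.10 (n = 22) in HGOSC and 5.63 ± 0.61 (n = 6) in HOSE, read by 1 probe set. AGR3 was 7.51-fold lower in HGOSC than in LMP and LGOSC pooled (log2 difference −2.91, SE 0.47, limma adjusted p = 3.34e-06), and all 22 HGOSC specimens lay below the median of the pooled group. The permutation p was 1e-05, the smallest that the permutations can give (6e-05 adjusted over the 6 comparisons). It was 3.76-fold lower in HGOSC than in LGOSC (−1.91, SE 0.43, adjusted p = 1.80e-04, 20 of 22 below the median of LGOSC). LGOSC lay 6.13-fold below LMP (−2.62, SE 0.55, adjusted p = 2.97e-04, exact p = 0.00181). Against HOSE, AGR3 was 28.2-fold higher in LMP (4.82, SE 0.66, adjusted p = 2.90e-07, exact p = 3.33e-04) and 4.60-fold higher in LGOSC (2.20, SE 0.60, adjusted p = 0.0015, exact p = 0.0123). HGOSC and HOSE differed by 0.29 (SE 0.56, adjusted p = 0.722, exact p = 0.553), less than the spread between specimens. Both means lay below the median of every array on this scale (6.14 to 6.61), so AGR3 was dim in both groups and a difference may be understated. The paralogue AGR2 was also highest in LMP, at 9.36 ± 1.58 (n = 8) against 7.09 ± 1.37 (n = 13) in LGOSC, 6.59 ± 1.42 (n = 22) in HGOSC and 6.51 ± 0.69 (n = 6) in HOSE. AGR2 was lower in HGOSC than in LMP and LGOSC pooled (−1.37, SE 0.48, adjusted p = 0.0145; −2.04 with the array set as a block, adjusted p = 0.0538) and lower in LGOSC than in LMP (−2.27, SE 0.60, adjusted p = 0.00354; −2.34 with the block). Within the array sets the latter was −4.12 in the high set (adjusted p = 0.00132) and turned to 0.59 in the middle set, on 2 LGOSC. The former was −2.04 in the middle set (limma adjusted p = 0.0259), on 5 LMP and 2 LGOSC. The difference between HGOSC and LGOSC did not pass (−0.50, adjusted p = 0.358).

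**Figure D1:**
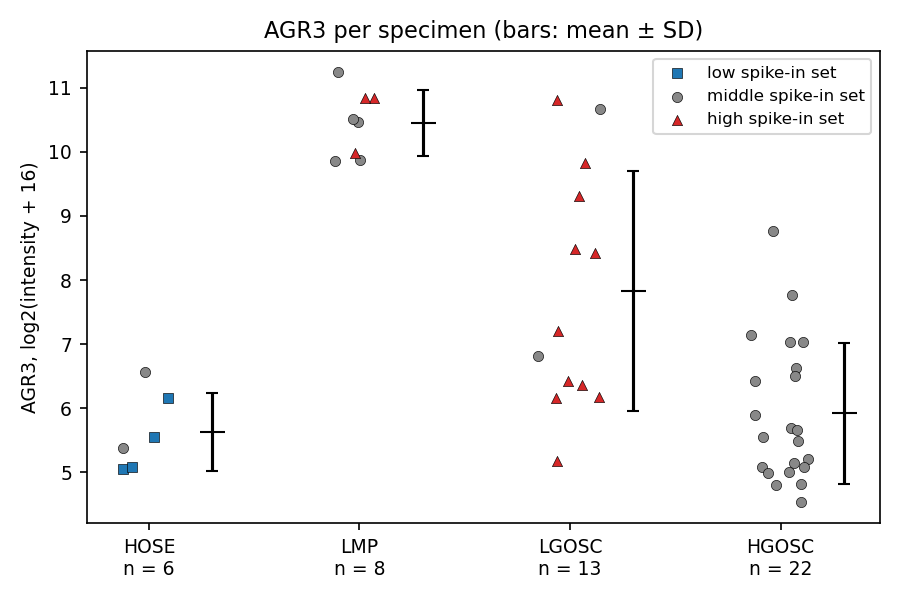
AGR3 in each specimen, as log2(intensity + 16), by group, with the mean and SD as bars and the symbol giving the spike-in array set. The 8 LMP specimens lie between 9.85 and 11.24, and the HGOSC specimens between 4.54 and 8.77.

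The spike-in controls, transcripts of the hybridisation cocktail, split the arrays into 3 sets that followed the groups in part. The high set (mean log2 13.55) held 14 arrays, namely 11 LGOSC and LMP 3, 7 and 8. The middle set (11.27) held 31 arrays, namely all 22 HGOSC, 5 LMP, 2 LGOSC and HOSE 5 and 6. The low set (9.84) held HOSE 1 to 4. Whether equal amounts were added to each sample is not given in the sources used here. The 3′ to 5′ log2 ratio of ACTB, a sign of RNA quality, was 4.25 ± 0.56 (SD, n = 6) in HOSE, 5.44 ± 0.50 (n = 22) in HGOSC, 5.76 ± 0.44 (n = 8) in LMP and 6.35 ± 0.49 (n = 13) in LGOSC. That of GAPDH was 2.28 ± 0.18, 2.14 ± 0.52, 2.96 ± 1.49 and 4.38 ± 1.49 in the same order. With the array set as a block, AGR3 differed by −4.00 (SE 0.63, adjusted p = 2.62e-05) between HGOSC and LMP with LGOSC, by −2.27 (adjusted p = 0.0301) between HGOSC and LGOSC, and by −2.42 (adjusted p = 0.00879) between LGOSC and LMP. The blocked difference from HOSE was 4.63 (adjusted p = 0.00189) for LMP, 2.22 (SE 1.09, adjusted p = 0.266) for LGOSC and −0.05 (adjusted p = 0.975) for HGOSC. As the low set holds HOSE alone, blocked differences from HOSE, here and below, take the HOSE level from HOSE 5 and 6 only. In the middle set alone, AGR3 was lower in the 22 HGOSC than in the 7 LMP and LGOSC specimens (−4.00, SE 0.49, adjusted p = 1.07e-06, exact p = 3.84e-06). These 7 are 5 LMP and 2 LGOSC, against 8 and 13 over all arrays. Pooled middle-set and blocked values, here and below, thus set HGOSC mainly against LMP. The middle-set value was −2.82 for HGOSC against 2 LGOSC, which did not pass (limma adjusted p = 0.0789, exact p = 0.0217 and 0.0652 adjusted over the 6 comparisons). It was −1.65 for 2 LGOSC against 5 LMP (exact p = 0.238) and 4.41 for 5 LMP against 2 HOSE (limma adjusted p = 0.00226, exact p = 0.0476 and 0.0952 adjusted). For 2 LGOSC against 2 HOSE it was 2.77, in a design that cannot give an exact p below 0.333. Within the high set, 11 LGOSC lay below 3 LMP by −2.88, which did not pass in limma (adjusted p = 0.0713, exact p = 0.022).

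Between HGOSC and the borderline and low-grade tumours, cell division genes were higher and genes of motile cilia were lower. All 34 measured mitosis genes were higher in the 22 HGOSC than in the 21 LMP and LGOSC specimens (34 adjusted over the list alone), with a mean log2 difference of 1.75 (adjusted p = 7.03e-28, and 0.0275 with an estimated correlation). The largest were DLGAP5, a spindle protein (2.80, SE 0.21), the kinesin KIF2C (2.68, SE 0.22), the spindle checkpoint kinase TTK (2.61, SE 0.23) and NUSAP1 (2.45, SE 0.30). Of 26 ciliated cell genes, 22 were lower and 1 higher, the same counts adjusted over the list alone, with a mean of −1.85 (adjusted p = 2.95e-09). That call was lost with an estimated correlation (adjusted p = 0.388). FOXJ1, the master transcription factor of motile cilia, differed by −2.78 (SE 0.31), RSPH1 of the radial spoke by −3.19 (SE 0.32) and CAPS by −3.01 (SE 0.33). The mitosis shift within the middle set was 1.83 (32 of 34 higher) and the ciliated shift −2.28 (22 of 26 lower), each with an adjusted p of 0.00117 with an estimated correlation. The block gave the same shifts, as all HGOSC arrays lie in the middle set.

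Genes of S phase and DNA repair went with mitosis. Of 26 DNA replication and G1/S genes, 19 were higher and 1 lower (20 and 1 adjusted over the list alone), with a mean of 0.83 (adjusted p = 1.12e-07, and adjusted p = 0.267 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, was higher by 2.53 (SE 0.24), GINS1 by 1.80 and CCNE2 (cyclin E2) by 1.78. The origin licensing factor CDT1 was higher by 2.17 over all arrays and differed by −0.32 within the middle set. Of 10 homologous recombination genes, 6 were higher and 1 lower (mean 0.54, adjusted p = 0.00857, and adjusted p = 0.388 with an estimated correlation), led by RAD51AP1 (2.60, SE 0.26) and FANCI (1.21), while XRCC2 differed by −1.75 (−0.45 within the middle set, adjusted p = 0.424). Replication shifted within the middle set by 1.10 (19 of 26 higher) and recombination by 0.87 (6 of 10 higher), both with an adjusted p of 0.008 with an estimated correlation.

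Targets of p53 were lower in HGOSC. Of 23 measured, 18 were lower and 2 higher (the same adjusted over the list alone), with a mean of −1.02 (adjusted p = 1.63e-05, and adjusted p = 0.194 with an estimated correlation). The cell cycle inhibitor CDKN1A (p21) fell by 1.94 (SE 0.25), the kinase PLK2 by 2.61 (SE 0.40), the death receptor TNFRSF10B by 1.79 (SE 0.22) and SPATA18, a mitochondrial quality gene, by 4.39 (SE 0.42). The middle-set shift was −0.99 (11 of 23 lower, adjusted p = 0.0015 with an estimated correlation). MAPK pathway output, the transcripts that follow RAS and RAF signalling, had 12 of 16 lower and 1 higher (mean −0.89, adjusted p = 0.0109, and adjusted p = 0.504 with an estimated correlation). The ERK phosphatase DUSP4 was lower by −2.95 (SE 0.38) and by −2.92 within the middle set, where 1 of 16 members was lower. SPRY2 differed by −1.41, ETV1 by −1.25 and IER3 by −1.24. Among 19 immediate early genes, 12 were lower and 1 higher (14 and 1 adjusted over the list alone; mean −1.06, adjusted p = 0.00857, and adjusted p = 0.71 with an estimated correlation). They included DUSP1 (−2.47), FOS (−2.04), FOSB (−1.89) and ATF3 (−1.82). That call was lost without probe sets that can match several transcripts (mean −0.85, adjusted p = 0.0736). Of these 19, 1 was lower within the middle set, with a mean of −0.60.

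Interferon response genes were higher in HGOSC, 14 of 22, with 2 lower (the same adjusted over the list alone; mean 0.95, adjusted p = 2.01e-04, and adjusted p = 0.624 with an estimated correlation). IFI6 was higher by 3.16 (SE 0.33), the T cell chemokines CXCL10 by 2.80 (SE 0.53) and CXCL11 by 2.35 (SE 0.45), and IFIT1 by 2.26 (SE 0.40). The middle-set mean was 1.26, 8 of 22 were higher and IFI6 differed by 3.41. Of 19 fibroblast and matrix genes 7 were higher (5 adjusted over the list alone; mean 0.79, adjusted p = 0.015, and adjusted p = 0.743 with an estimated correlation). Among them were LUM (1.74, SE 0.62), COL5A2 (1.43), DCN (1.24) and POSTN (2.33), which encode proteins of the connective tissue matrix. LUM differed by 2.88 and POSTN by −0.08 within the middle set, where 11 of the 19 were higher (mean 1.64). Of 14 T and NK cell genes 6 were higher (6 adjusted over the list alone), with small differences such as PRF1 (1.06), CD2 (0.82), CCL5 (0.58) and CD3E (0.52). That list shifted by 0.33 (adjusted p = 0.0411, and adjusted p = 0.71 with an estimated correlation), with a mean of 0.20 within the middle set. These 4 genes stood at 0.09, 0.41, −0.25 and −0.02 there, and none of the 4 passed in limma (adjusted p of at least 0.431). Without the 8 HGOSC arrays of narrow intensity range, the T and NK cell genes shifted by 0.13 and were not called (adjusted p = 0.331), and leaving out 1 specimen ended the call in 8 of 43 refits. Quantile normalisation ended the T and NK cell call at a larger mean (0.43, adjusted p = 0.0725), and leaving out probe sets that can match several transcripts ended the fibroblast call (0.42, adjusted p = 0.157).

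The other 14 lists were not called in this comparison. Macrophage and monocyte genes had a mean of 0.55 (4 of 13 higher, adjusted p = 0.0596), among them AIF1 (1.73), FCER1G (1.57) and CD163 (1.12). Within the middle set these 3 stood at −0.09, 0.44 and 0.87 and did not pass (adjusted p = 0.918, 0.56 and 0.254). Endothelium stood at 0.37 (5 of 12 higher and 1 lower, adjusted p = 0.228). MHC class II genes, which present antigen, had a mean of −0.62 with 5 of 10 lower (adjusted p = 0.228), namely among others HLA-DMA (−1.37), HLA-DOA (−1.20), HLA-DPA1 (−1.03) and CD74 (−0.98). Oestrogen response genes had a mean of −0.71 with 9 of 16 lower and 1 higher (adjusted p = 0.228), with TFF3 at −2.09, GREB1 at −2.01, PGR at −1.71 and CA12 at −1.64. Serous and secretory epithelium had a mean of −0.46 (2 of 24 higher and 7 lower, adjusted p = 0.436), with MUC16 at −2.58, LCN2 at −1.40, SOX17 at −1.17 and MSLN at −1.10. CDK inhibitors and the RB pathway stood at −0.23 (3 of 15 higher and 5 lower, adjusted p = 0.888), with CCND1 at −1.19 and CCND3 at −1.10. The means were 0.12 for mesenchymal transcription (adjusted p = 0.301), 0.06 for hypoxia and glycolysis (adjusted p = 0.428), 0.29 for red blood cell genes (adjusted p = 0.697) and −0.14 for epithelial junction and keratin (adjusted p = 0.89). B and plasma cell genes had a mean of 0.14, with an upward test, and a median of −0.04 (adjusted p = 0.622). In 3 lists the mean was below 0 while the median and the test were above it. These were mesothelium and ovarian surface (mean −0.21, median 0.07, adjusted p = 0.702), ovarian stroma (−0.27 and 0.04, adjusted p = 0.805) and endoplasmic reticulum folding (−0.01 and 0.16, adjusted p = 0.781).

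**Figure D2:**
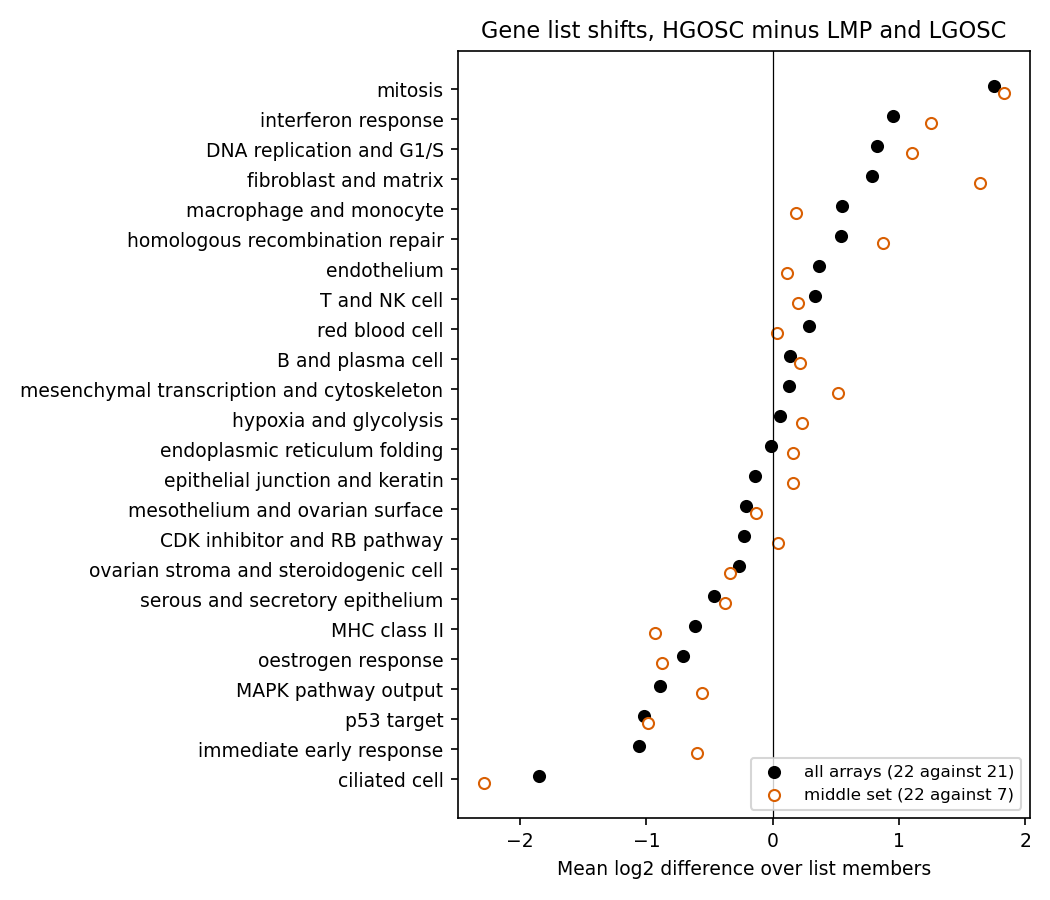
Mean log2 difference of each gene list between HGOSC and LMP with LGOSC, over all arrays (filled, 22 against 21) and within the middle array set (open, 22 against 7). Mitosis lies highest at 1.75 and ciliated cell genes lowest at −1.85 over all arrays, and the fibroblast mean moves from 0.79 to 1.64 within the set. The set keeps 5 of 8 LMP and 2 of 13 LGOSC specimens. Those 2 LGOSC had fibroblast scores of −0.82 and −1.27, against a mean of 0.02 over all LGOSC.

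Across all genes, 2881 passed between HGOSC and LMP with LGOSC, 1046 higher and 1835 lower. The 10 genes of smallest log2 difference chosen by the fixed rule were SPATA18 (−4.39, SE 0.42, adjusted p = 5.90e-11), CFAP43 (−4.06, SE 0.34), FAM81B (−3.90, SE 0.44), PLEKHS1 (−3.85, SE 0.55), CIMIP1 (−3.78, SE 0.55), AGBL2 (−3.64, SE 0.31), ALKAL2 (−3.63, SE 0.49), CFAP52 (−3.63, SE 0.43), CFAP126 (−3.60, SE 0.42) and CFAP70 (−3.60, SE 0.32). The 4 CFAP genes encode proteins of the ciliary axoneme. Within the middle set these 10 differed by −4.88 (SPATA18) to −3.43 (CFAP70). The 10 of largest difference were ZBTB33 (4.44, SE 0.67), ABI1 (4.30, SE 0.68), EGFR (3.95, SE 0.64), PCDHB9 (3.94), CLNK (3.90), DYNLT2 (3.77), AP3B2 (3.74), TAF1C (3.71), ANKRD30BP3 (3.65) and SYCP3 (3.51). Within the middle set they differed by −0.30 to 0.32, the smallest adjusted p being 0.367 for DYNLT2. Other probe sets of ZBTB33 (−0.19) and TAF1C (−1.60) went the other way, and the 8 others of EGFR ranged from −1.15 to 4.12. The second probe set of SPATA18 stood at −0.16. Among tumour markers, CDKN2A (p16) was higher by 1.26 (SE 0.37, adjusted p = 0.00405) and MKI67, the Ki-67 proliferation antigen, by 0.44 (SE 0.11, adjusted p = 9.19e-04). MUC16, which encodes CA-125, was lower by −2.58 (SE 0.35, adjusted p = 1.47e-07). The progesterone receptor PGR differed by −1.71 (SE 0.54, adjusted p = 0.00694), the oestrogen receptor ESR1 by −0.79 (adjusted p = 0.0132), PAX8 by −0.56 (adjusted p = 0.00981) and WT1 by −0.47 (adjusted p = 0.146). The other probe set of PGR stood at 0.45, those of CDKN2A ranged from −0.82 to 1.34, and 2 of the 7 others of ESR1 went the same way. Of 62 genes with other probe sets among those read for agreement in this comparison, 25 had at least 1 that went the other way and in 9 all did. These counts were 31 and 12 of 61 for HGOSC against LGOSC, 23 and 7 of 47 for LGOSC against LMP, and 19 and 6 of 52, 31 and 18 of 62 and 19 and 7 of 53 for LMP, LGOSC and HGOSC against HOSE. Within the middle set PAX8 stood at 0.05, ESR1 at −0.63 (adjusted p = 0.475) and CDKN2A at 1.30 (adjusted p = 0.196), and PGR at −2.81. In that set 848 genes passed (263 higher and 585 lower, 693 of them among the 2881 and in the same direction), and 804 passed with the block. Quantile normalisation turned the balance of higher to lower genes from 36.3% higher to 56.1%, and scaling to the 75th percentile to 50.3%, moving the median of all genes from −0.06 to 0.07 and 0.08.

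**Figure D3:**
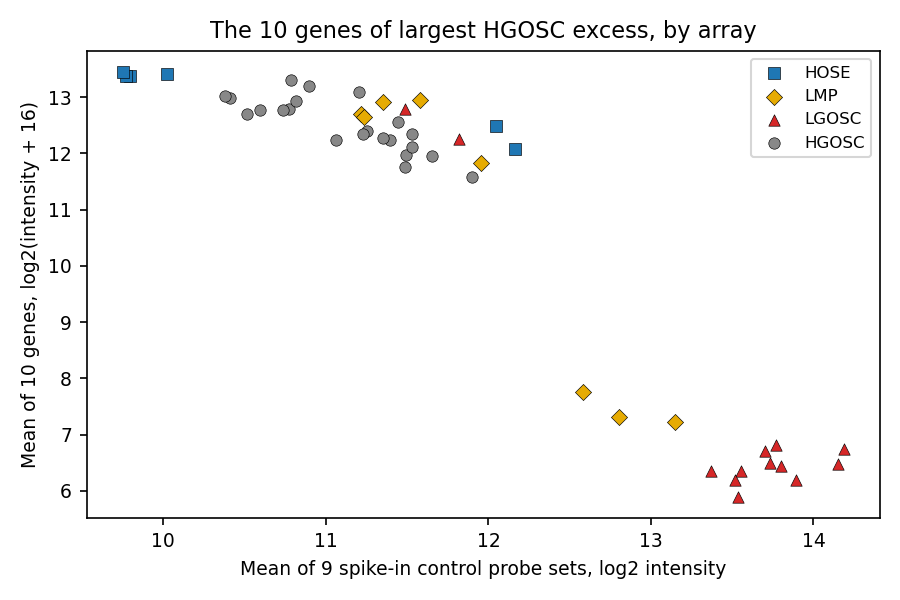
Mean log2(intensity + 16) of the 10 genes of largest HGOSC excess against the mean log2 intensity of the 9 spike-in control probe sets, 1 point per array. The 14 arrays of the high set, with a spike-in mean of 12.58 to 14.19, form a separate low group that holds LMP as well as LGOSC arrays.

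HGOSC against LGOSC compares grade within serous carcinoma. Again mitosis genes were higher (32 of 34, and 33 adjusted over the list alone; mean 1.75, adjusted p = 6.74e-19, and adjusted p = 0.194 with an estimated correlation), with DLGAP5 at 3.03 (SE 0.23), TTK at 2.70 (SE 0.26), KIF2C at 2.68 and NUSAP1 at 2.47. Replication genes were higher in 18 of 26 and lower in 2 (mean 0.78, adjusted p = 1.56e-04, and adjusted p = 0.775 with an estimated correlation), with RRM2 at 2.91 (SE 0.26). MCM10 stood at −1.63 on the probe set used, while its 2 other probe sets gave 1.17 and 1.40. Ciliated cell genes were lower in 20 of 26 and higher in 1 (mean −1.31, adjusted p = 6.22e-04, and adjusted p = 0.964 with an estimated correlation), with CFAP126 at −3.03 (SE 0.43), RSPH1 at −2.72 and FOXJ1 at −2.42 (SE 0.32). The mean ciliated cell score was 1.68 in LGOSC 4, 6 and 8, −0.12 in the other 10 LGOSC and −0.49 in HGOSC, so the shift is not spread evenly over LGOSC. Of 23 p53 targets 16 were lower and 2 higher (17 and 2 adjusted over the list alone; mean −0.89, adjusted p = 0.0108, and adjusted p = 0.775 with an estimated correlation), PLK2 standing at −2.56 and TNFRSF10B at −1.94. Interferon genes were higher in 11 of 22 and lower in 3 (mean 0.84, adjusted p = 0.0108, and adjusted p = 0.964 with an estimated correlation), led by IFI6 (3.21, SE 0.36) and CXCL10 (2.67). With the array set as a block, mitosis stood at 1.87 (29 of 34 higher), replication at 1.16 (15 of 26 higher) and ciliated cell genes at −1.24 (9 of 26 lower). Within the middle set, which holds 2 LGOSC, the means were 2.03, 1.28 and −1.73 for these 3 lists, −0.52 for p53 targets and 0.99 for interferon genes.

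Between HGOSC and LGOSC 4176 genes passed, 1576 higher and 2600 lower. The genes of smallest difference were ANKRD36B (−4.27, SE 0.48), the non-coding RMST (−4.27, SE 0.45), SPATA18 (−3.85, SE 0.44), CFAP70 (−3.74, SE 0.36) and CFAP43 (−3.58, SE 0.35). Blocked by array set they stood at −2.73, −2.69, −3.86, −3.67 and −3.80. The genes of largest difference, ZBTB33 (5.92), ABI1 (5.77), EGFR (5.32), DYNLT2 (5.14) and PCDHB9 (5.12), had blocked values of 0.78, 0.55, 0.40, 0.35 and 0.24. CDKN2A was higher by 1.46 (adjusted p = 0.00203) and MUC16 lower by −2.89 (SE 0.39, adjusted p = 3.13e-08). PAX8 differed by −0.90 (adjusted p = 6.1e-05) and ESR1 by −0.79 (adjusted p = 0.0361). With the block CDKN2A stood at 1.81 (adjusted p = 0.0732), PAX8 at −0.38 (adjusted p = 0.44), ESR1 at −0.52 (adjusted p = 0.573) and MUC16 at −2.35 (adjusted p = 0.0099). Of the 7 other ESR1 probe sets 1 went the same way, and the single other ones of PGR (0.71) and SPATA18 (0.05) did not. MKI67 (0.31, adjusted p = 0.072), PGR (−0.62, adjusted p = 0.294) and WT1 (−0.59, adjusted p = 0.123) did not pass. The block left 980 genes, 836 of them shared in direction, and the middle set 243. Quantile normalisation gave 56.5% higher against 37.7%, and the 75th percentile 53.4%, and the former moved the median of all genes from −0.06 to 0.11, so that genes counted as higher or lower are relative to that shift.

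LGOSC against LMP compares invasive low-grade carcinoma with borderline tumour, the groups that the series pooled. Ciliated cell genes were lower in LGOSC in 18 of 26 (21 adjusted over the list alone), with a mean of −1.42 (adjusted p = 2.38e-10, and adjusted p = 0.994 with an estimated correlation). They included SNTN of the ciliary tip (−2.87, SE 0.45), the radial spoke gene RSPH4A (−2.65, SE 0.49), TEKT1 (−2.36, SE 0.45) and CIMAP3 (−2.27, SE 0.45). Their blocked mean was −1.46 (14 of 26 lower), −1.88 within the high set (11 against 3, 4 lower) and −0.78 within the middle set (2 against 5), where no member passed in limma. The ciliated score of LGOSC 4, 6 and 8 (mean 1.68) was as high as that of LMP (mean 1.28), and the other 10 LGOSC had a mean of −0.12. Of 19 fibroblast and matrix genes 6 were higher and 1 lower (8 and 1 adjusted over the list alone; mean 1.13, adjusted p = 0.0392, and adjusted p = 0.994 with an estimated correlation), with PDGFRB at 2.49 (SE 0.71), THBS2 at 2.43 (SE 0.70), COL5A1 at 2.19 (SE 0.72) and TAGLN at 2.07 (SE 0.38). That mean was 0.70 with the block, 1.40 within the high set and −0.47 within the middle set, and its call ended without probe sets that can match several transcripts, at a mean of 1.22 (adjusted p = 0.0504). The call also ended in 9 of 21 refits that left out 1 specimen, with the highest adjusted p at 0.152 without LGOSC 2. The fibroblast score ranged from −1.27 to 1.69 among LGOSC, highest in LGOSC 1 and 2, against −0.98 to −0.42 in LMP, and 6 of the 13 LGOSC lay no higher than the highest LMP. Mitosis genes had a mean of 0.01 with 1 of 34 lower (adjusted p = 0.953). PGR was lower in LGOSC (−2.87, SE 0.65, adjusted p = 7.52e-04; −2.74 with the block) and PAX8 higher (0.89, SE 0.24, adjusted p = 0.00422), a call lost with the block (0.60, adjusted p = 0.134) and within the high set (0.47, adjusted p = 0.349). MUC16 (0.79), MKI67 (0.37), CDKN2A (−0.52), ESR1 (0.00) and WT1 (0.32) did not pass.

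In all, 2026 genes passed between LGOSC and LMP, 1117 higher and 909 lower. RBM6 (3.77, SE 0.52), RMST (3.63, SE 0.57), RASEF (3.51, SE 0.52), ANKRD36B (3.39, SE 0.62) and the metalloproteinase inhibitor TIMP3 (3.23, SE 0.73) had the largest differences, with blocked values of 3.13, 2.75, 2.93, 2.53 and 2.77. The smallest were ZBTB33 (−3.88, blocked −1.02), ABI1 (−3.85, blocked −0.95), the serine protease inhibitor SERPINA5 (−3.82, SE 0.99, blocked −3.30 with adjusted p = 0.0549), DYNLT2 (−3.58, blocked −0.91) and EGFR (−3.58, blocked −0.84). The block left 723 genes (656 shared in direction) and the high set 1248. Within the middle set 0 genes passed in limma, against 351 at an unadjusted p under 0.05. Quantile normalisation gave 37.4% higher against 55.1%, and scaling to the 75th percentile 40.1%, with the median of all genes moving from −0.02 to −0.13 and −0.14.

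Borderline tumours differed from ovarian surface epithelium in the genes that mark each kind of epithelium. In the 8 LMP against 6 HOSE specimens, 24 of 26 ciliated cell genes were higher (mean 2.90, adjusted p = 8.49e-14, and adjusted p = 0.0887 with an estimated correlation), such as CFAP126 (5.45, SE 0.66), CAPS (4.93, SE 0.50), FOXJ1 (4.91, SE 0.50) and RSPH4A (4.50, SE 0.58). Serous and secretory genes were higher in 17 of 24 (18 adjusted over the list alone; mean 2.67, adjusted p = 8.87e-09, and adjusted p = 0.0599 with an estimated correlation), among them SCGB2A1 (6.33, SE 0.93), LCN2 (4.79, SE 0.79), SOX17 (4.60, SE 0.46) and WFDC2, which encodes HE4 (4.43, SE 0.39). Epithelial junction and keratin genes were higher in 13 of 15 (14 adjusted over the list alone; mean 1.82, adjusted p = 1.24e-06, and adjusted p = 0.0887 with an estimated correlation), such as the splicing factor ESRP1 (3.61), EPCAM (3.45, SE 0.31), CLDN3 (3.22) and CDH1, E-cadherin (2.07). Mesothelium and ovarian surface genes were lower in 8 of 13 and higher in 1 (10 and 1 adjusted over the list alone; mean −2.39, adjusted p = 1.04e-08, and 0.00476 with an estimated correlation). They were led by ITLN1 (−5.66, SE 0.36), BNC1 (−5.38, SE 0.67), ALDH1A2 (−5.02, SE 0.78) and calretinin, CALB2 (−4.50, SE 0.50). The second probe set of ALDH1A2 stood at 0.18. With the block the 4 means were 3.14, 2.48, 0.94 and −3.50, with 19, 12 and 5 members higher and 7 lower.

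Several lists for other cell types were called lower in LMP than in HOSE. All 4 red blood cell genes were lower (mean −2.64, adjusted p = 1.88e-04, and 0.00819 with an estimated correlation), with HBB at −3.59 (SE 0.52). HBB stood at 14.01 in the 2 HOSE of the middle set and at 9.91 in the 4 of the low set. Fibroblast and matrix genes were lower in 8 of 19 (mean −1.41, adjusted p = 5.31e-04, and adjusted p = 0.403 with an estimated correlation), such as DCN (−3.71) and PDGFRA (−3.03), with a blocked mean of −2.84. Ovarian stroma and steroidogenic genes were lower in 6 of 9 (mean −0.72, adjusted p = 0.00127, and adjusted p = 0.0887 with an estimated correlation), such as FOXL2 (−1.92) and STAR (−1.87). Macrophage genes were lower in 5 of 13 (mean −1.02, adjusted p = 0.00387, and adjusted p = 0.403 with an estimated correlation), and endothelial genes in 5 of 12 with 1 higher (mean −0.71, adjusted p = 0.0226, and adjusted p = 0.215 with an estimated correlation), KDR standing at −4.04 (SE 0.35). With the fibroblast score as a covariate the macrophage (mean −0.63, adjusted p = 0.0629) and endothelial (−0.68, 0.0750) calls were lost. The latter was also lost at an unchanged mean when only the 2 groups were fitted (−0.71, 0.0599). Mesenchymal transcription genes were lower in 6 of 10 and higher in 1 (mean −1.08, adjusted p = 0.00214, and adjusted p = 0.206 with an estimated correlation), with the repressors SNAI2 (−2.44), TWIST1 (−2.12) and ZEB1 (−2.09) lower and CDH2 (1.78) higher.

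Of the lists for processes, 5 more were called higher in LMP than in HOSE. Of 23 p53 targets 16 were higher and 2 lower (17 and 2 adjusted over the list alone; mean 1.23, adjusted p = 3.28e-04, and adjusted p = 0.109 with an estimated correlation), including SPATA18 (4.89, SE 0.68), the p53 ligase MDM2 (2.43, SE 0.27) and RRM2B (2.29). MAPK output was higher in 9 of 16 (mean 1.26, adjusted p = 0.0212, and adjusted p = 0.403 with an estimated correlation), with CCND1 at 3.47 and DUSP4 at 3.45 (SE 0.62). Hypoxia and glycolysis genes were higher in 10 of 17 (mean 0.91, adjusted p = 0.0151, and adjusted p = 0.403 with an estimated correlation), MHC class II genes in 8 of 10 (mean 1.60, adjusted p = 0.0153, and adjusted p = 0.403 with an estimated correlation) and replication genes in 12 of 26 with 1 lower (mean 0.77, adjusted p = 0.0226, and adjusted p = 0.487 with an estimated correlation). Examples are hexokinase HK2 (2.69), CD74 (2.32) and UHRF1 (2.13). With quantile normalisation the MAPK, hypoxia and MHC class II calls were lost, at adjusted p = 0.0640, 0.0798 and 0.0798. Their means were then 0.9996, 0.59 and 1.18. That of hypoxia was also lost with the mean of all probe sets (0.54, adjusted p = 0.0861) and without probe sets that can match several transcripts (0.61, 0.394). The replication call was lost with the 60th percentile filter (mean 0.77, adjusted p = 0.0532), the mean of all probe sets (0.50, 0.0686) and without probe sets that can match several transcripts (0.59, 0.122). Blocked by array set, p53 targets had a mean of 0.79 with 3 members higher, MAPK output 0.48 with 1, and replication 0.50.

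Between LMP and HOSE 5031 genes passed, 3393 higher and 1638 lower, the most different being SCGB2A1, CLDN10 (5.90, SE 0.84), CIMIP1 (5.86, SE 0.79), PLEKHS1 (5.85, SE 0.89) and MECOM (5.77, SE 0.48) among higher genes. ITLN1, BNC1, NPY1R (−5.37, SE 0.47), ALDH1A2 and BCHE (−4.90, SE 0.75) were the lowest, and the blocked values of these 10 went the same way, from −7.43 for BCHE to 6.87 for SCGB2A1. Of the 3 other probe sets of MECOM 1 went the same way. PAX8, a Müllerian lineage factor, was higher by 3.12 (SE 0.29, adjusted p = 1.29e-11; 3.33 with the block), MUC16 by 4.12 (SE 0.61; 2.50 with the block, adjusted p = 0.0832) and ESR1 by 2.11 (SE 0.51, adjusted p = 0.00129; 0.59 with the block). MKI67 was lower by −0.84 (adjusted p = 0.00359) and stood at 0.11 with the block, with 1 of its 3 other probe sets going the same way. AGR2 was higher by 2.85 (SE 0.72, adjusted p = 0.00189; 2.68 with the block, adjusted p = 0.151). The block left 1023 genes (692 shared in direction), and the middle set 865 on 5 LMP and 2 HOSE. The count was 854 without HOSE 1 to 4, 7816 without HOSE 5 and 6 and 8128 with array weights. Quantile normalisation gave 54.9% higher against 67.4%.

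LGOSC differed from HOSE along the same epithelial lists. Serous and secretory genes were higher in 18 of 24 and lower in 2 (mean 2.44, adjusted p = 2.06e-04, and adjusted p = 0.341 with an estimated correlation), with MUC16 at 4.91 (SE 0.56; 2.99 with the block, adjusted p = 0.0696), SCGB2A1 at 4.74 (SE 0.85) and SOX17 at 4.68 (SE 0.42). Junction genes were higher in 12 of 15 (13 adjusted over the list alone; mean 1.87, adjusted p = 8.37e-04, and adjusted p = 0.398 with an estimated correlation), with EPCAM at 3.10 (SE 0.28). Ciliated cell genes were higher in 19 of 26 and lower in 1 (mean 1.48, adjusted p = 0.0184, and adjusted p = 0.692 with an estimated correlation), FOXJ1 standing at 3.95 (SE 0.46) and CAPS at 3.45. The ciliated call was lost with the 3′ to 5′ ratio as a covariate (mean 1.20, adjusted p = 0.112) and, at the same mean, when only the 2 groups were fitted (0.0550). The mean ciliated cell score was 1.68 in LGOSC 4, 6 and 8, −0.12 in the other 10 LGOSC and −0.57 in HOSE, so that 3 specimens carry much of this shift. Leaving out 1 specimen ended the call in 3 of 19 refits, among them that without LGOSC 8 (adjusted p = 0.0540). Mesothelial genes were lower in 9 of 13 and higher in 1 (mean −2.32, adjusted p = 3.64e-05, and 0.0469 with an estimated correlation), with BNC1 at −5.75 (SE 0.61) and ITLN1 at −5.66 (SE 0.33). The blocked means of the 4 lists were 2.10, 0.72, 1.68 and −3.48. Red blood cell genes were lower in 4 of 4 (mean −2.83, adjusted p = 0.00363, and 0.0469 with an estimated correlation). Macrophage genes were lower in 6 of 13 (mean −1.36, adjusted p = 0.0103, and adjusted p = 0.692 with an estimated correlation), such as AIF1 (−3.31) and FCER1G (−2.98). Ovarian stroma genes were lower in 6 of 9 and higher in 1 (mean −0.88, adjusted p = 0.0184, and adjusted p = 0.341 with an estimated correlation), with STAR at −2.34. That call was lost with a pseudocount of 1 (mean −0.90, adjusted p = 0.0536), a filter at the 60th percentile (−0.73, 0.148) and without probe sets that can match several transcripts (−0.81, 0.0737).

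Of 7474 genes past the threshold between LGOSC and HOSE, 4723 were higher and 2751 lower. SLC4A11 (5.48, SE 0.57), LYPD1 (5.30, SE 0.63), MECOM (5.21, SE 0.44), FZD10 (5.16, SE 0.67) and CP, ceruloplasmin (5.14, SE 0.65), had the largest differences, and 5.04, 4.84, 5.11, 4.18 and 6.27 with the block. A second probe set of SLC4A11 went the other way, and 2 of the 3 others of MECOM went the same way. ABI1 (−6.36), ZBTB33 (−6.25), EGFR (−6.21), CLNK (−6.17) and PCDHB9 (−6.08) had the smallest, and −0.35, −0.93, 0.04, 0.13 and 0.35 with the block. PAX8 was higher by 4.01 (SE 0.26, adjusted p = 1.49e-16; 3.93 with the block) and ESR1 by 2.11 (adjusted p = 1.38e-04; 0.44 with the block), while PGR was lower by −2.33 (SE 0.71, adjusted p = 0.00413; −2.50 with the block, adjusted p = 0.289). Of the 7 other ESR1 probe sets 1 went the same way. AGR2 (0.58, adjusted p = 0.447), CDKN2A (0.36) and WT1 (0.85) did not pass, and MKI67 stood at −0.48 (adjusted p = 0.042; 0.37 with the block), with 1 of its 3 other probe sets going the same way. WT1 turned to −1.06 with the block (adjusted p = 0.461), and its other probe set stood at −0.82. With 11 of 13 LGOSC arrays in the high set and 4 of 6 HOSE arrays in the low set, the block left 567 genes, 428 of them shared in direction. The middle set gave 435 on 2 against 2. Quantile normalisation gave 51.7% higher against 63.2%, with the median of all genes at 0.13 against 0.27.

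HGOSC against HOSE set cell division beside the epithelial differences. Mitosis genes were higher in 31 of 34 (31 higher and 1 lower adjusted over the list alone; mean 2.23, adjusted p = 2.48e-27, and 0.0135 with an estimated correlation), led by CDK1 (4.19, SE 0.42), CDC20 (3.49, SE 0.39), KIF20A (3.44, SE 0.48) and BUB1B (3.41, SE 0.35). Replication genes were higher in 22 of 26 (mean 1.68, adjusted p = 1.23e-14, and 0.0182 with an estimated correlation), such as the helicase subunits MCM2 (3.39, SE 0.32) and MCM4 (2.78). Homologous recombination genes were higher in 7 of 10 (8 adjusted over the list alone; mean 1.02, adjusted p = 7.96e-04, and adjusted p = 0.0825 with an estimated correlation), with RAD51AP1 at 2.75 and BRIP1 at 2.46 (its other probe set at −0.27). Serous and secretory genes were higher in 17 of 24 (mean 2.07, adjusted p = 3.1e-10, and 0.0182 with an estimated correlation), with WFDC2 at 4.02 (SE 0.33) and EPCAM at 3.68 (SE 0.26). Junction genes were higher in 11 of 15 (13 adjusted over the list alone; mean 1.72, adjusted p = 2.66e-09, and 0.0233 with an estimated correlation). Mesothelial genes were lower in 8 of 13 (11 adjusted over the list alone; mean −2.55, adjusted p = 6.94e-12, and 4.63e-04 with an estimated correlation), with ITLN1 at −5.42 (SE 0.31) and CALB2 at −4.49 (SE 0.43). The blocked means of these 6 lists were 2.63, 1.58, 1.20, 2.00, 1.04 and −3.63. Ciliated cell genes did not differ as a list (mean 0.17, median −0.02, adjusted p = 0.969), although MLF1 (1.67, adjusted p = 0.0042) and FOXJ1 (1.54, adjusted p = 0.0056) were higher.

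Other lists called between HGOSC and HOSE were mostly lower. Red blood cell genes were lower in 3 of 4 (mean −2.47, adjusted p = 5.71e-05, and 0.00444 with an estimated correlation), with HBB at −4.36. Ovarian stroma genes were lower in 5 of 9 (8 adjusted over the list alone; mean −1.09, adjusted p = 5.85e-05, and 0.0182 with an estimated correlation), with STAR at −2.49 and DLK1 at −2.31. Mesenchymal transcription genes were lower in 4 of 10 (mean −0.63, adjusted p = 0.0214, and adjusted p = 0.372 with an estimated correlation) and macrophage genes in 1 of 13, VSIG4 at −1.35 (mean −0.68, adjusted p = 0.0214, and adjusted p = 0.543 with an estimated correlation). The macrophage call was lost with the 3′ to 5′ ratio as a covariate (mean −0.61, adjusted p = 0.0506) and without HOSE 1, whose macrophage score stood apart (mean −0.35, adjusted p = 0.169). Without HOSE 1 the macrophage shifts of LMP (−0.69, adjusted p = 0.0210) and LGOSC (−1.04, adjusted p = 0.0331) from HOSE were smaller and still called. The mesenchymal call was lost without HOSE 5 (adjusted p = 0.0674) or HOSE 6 (0.0824). Hypoxia and glycolysis genes were higher in 10 of 17 (mean 0.95, adjusted p = 1.83e-04, and adjusted p = 0.145 with an estimated correlation), such as HK2 (2.43) and VEGFA (2.08). Endoplasmic reticulum folding genes were higher in 6 of 14 and lower in 1 (mean 0.67, adjusted p = 0.0474, and adjusted p = 0.541 with an estimated correlation), with HSP90B1 at 1.67. Their mean was −0.20 with the block, and quantile normalisation ended their call (0.45, adjusted p = 0.291), as leaving out probe sets that can match several transcripts did that of hypoxia (0.53, adjusted p = 0.21). The folding call ended in 13 of 28 refits that left out 1 specimen.

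Of 2902 genes past the threshold between HGOSC and HOSE, 2105 were higher and 797 lower. The largest and smallest were MECOM (5.46, SE 0.41), LPAR3 (5.04, SE 0.77), KLHL14 (4.52, SE 0.49), SCGB2A1 (4.34, SE 0.80) and CDK1, and ITLN1, ALDH1A2 (−4.97, SE 0.67), BNC1 (−4.96, SE 0.57), NPY1R (−4.54, SE 0.40) and CALB2. Their blocked values went the same way, from −7.21 for ITLN1 to 5.91 for MECOM. Second probe sets of LPAR3 (−0.20) and KLHL14 (−0.28) stood near 0, and 1 of the 3 others of MECOM went the same way. PAX8 was higher by 3.11 (SE 0.24, adjusted p = 6.76e-14), CDKN2A by 1.82 (adjusted p = 0.00819; 1.93 with the block, adjusted p = 0.172), MUC16 by 2.02 (adjusted p = 0.00269; 0.64 with the block) and ESR1 by 1.32 (adjusted p = 0.0191; −0.08 with the block). PGR was lower by −2.95 (SE 0.66, adjusted p = 7.21e-04). AGR2 (0.08, adjusted p = 0.936), WT1 (0.26, adjusted p = 0.682) and MKI67 (−0.17, adjusted p = 0.52) did not pass. WT1 turned to −1.32 with the block (adjusted p = 0.212). All 3 other probe sets of MKI67 went the other way (0.53 to 1.71), and the probe set used stood at 0.87 (adjusted p = 0.0194) with the block. The block left 1210 genes (669 shared in direction), and 968 passed without HOSE 1 to 4. The count rose to 6222 with array weights, 5952 without HOSE 5 and 6 and 5053 without the 8 HGOSC arrays of narrow intensity range. Quantile normalisation gave 59.8% higher against 72.5%.

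In the fit without array set, the 3 tumour groups shared differences from HOSE. Higher in both LMP and LGOSC were 2669 genes and lower in both 1480, against 912 and 257 for independent lists. For LMP with HGOSC the counts were 1589 and 600 (407 and 74.3), and for LGOSC with HGOSC 1553 and 620 (566 and 125). The correlation of log2 differences across genes, which are not independent replicates, was 0.85, 0.78 and 0.71 for the 3 pairs, against 0.62, 0.67 and 0.73 in simulated unchanged groups that share their HOSE values. The simulation drew independent noise for every array, HOSE included, so it lacks the low and middle split of the real HOSE. The covariance was 1.15, 0.67 and 0.75, against 0.080 simulated in each. With HOSE split 3 and 3, so that the comparisons shared no HOSE array, the median covariance over 20 splits was 1.12, 0.63 and 0.73. The median correlation was then 0.81, 0.73 and 0.66, and the lowest 0.54, 0.30 and 0.23. These values are not separated from array set, as 4 of the 6 HOSE arrays form the low set, which holds no tumour array. With the array set as a block, 62.4%, 55.6% and 79.6% of the genes past the threshold in LMP, LGOSC and HGOSC against HOSE kept their sign. That fit takes the HOSE level from HOSE 5 and 6 alone.

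Whether AGR3 followed the ciliated cell genes was read within each group. In the 13 LGOSC, Pearson's r between AGR3 and the ciliated cell score was 0.76 (95% interval 0.37 to 0.93, permutation p = 0.00244, 0.00976 adjusted over the 4 groups). Spearman's rho was 0.68 (permutation p = 0.0140, adjusted 0.0561). Without the 2 specimens farthest from the median score r was 0.65 (adjusted permutation p = 0.104). A gap in the score between 0.35 and 1.45 set 3 LGOSC specimens apart, and in the 10 below it r was 0.27 (95% interval −0.43 to 0.77, permutation p = 0.452). The narrower score range there would lower r if 1 linear relation held throughout. This r therefore does not tell whether the 3 specimens carry the relation. In LMP r was 0.31 (n = 8, exact p = 0.452; rho 0.21, exact p = 0.619), in HOSE −0.12 (n = 6, exact p = 0.869; rho −0.20, exact p = 0.714) and in HGOSC −0.01 (n = 22, permutation p = 0.950; rho −0.07, p = 0.765). Without the 2 farthest specimens these became −0.24, 0.45 and −0.21. Within the 11 LGOSC of the high set r was 0.70 (permutation p = 0.0109; rho 0.63).

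**Figure D4:**
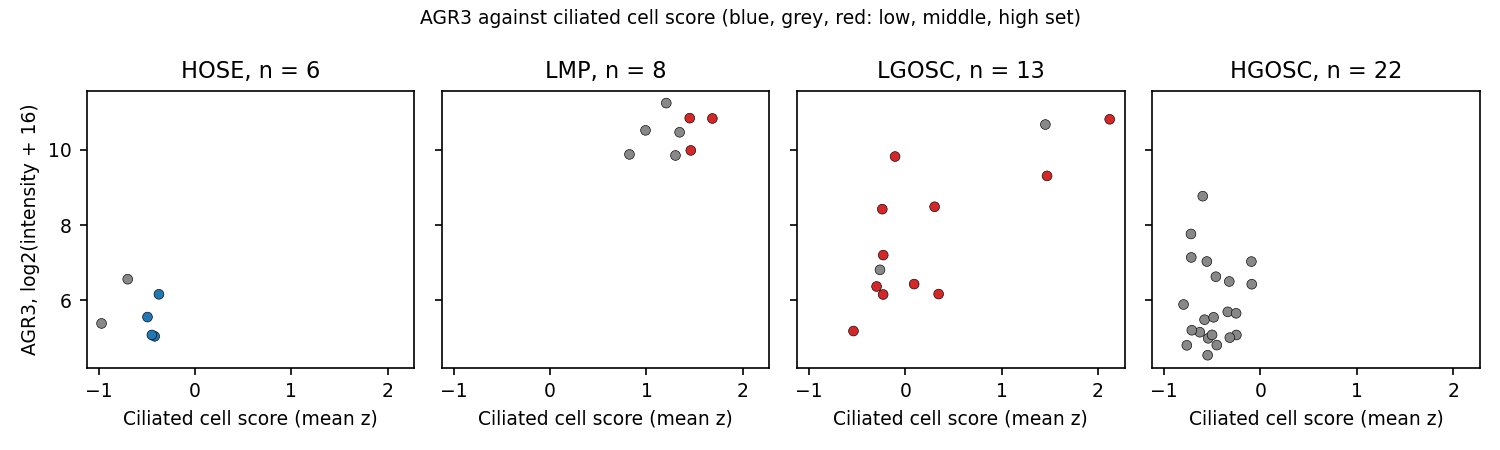
AGR3 as log2(intensity + 16) against the ciliated cell score (mean z-score of the list) in each specimen, 1 panel per group, with the colour giving the array set. In LGOSC 3 specimens with a score of at least 1.45 have AGR3 of at least 9.31, and the other 10 range from 5.19 to 9.82.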

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

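The tests of single specimens against the rest of their group were planned before the values were seen. In the 6 HOSE and 8 LMP specimens, each named gene and each list score was checked for a lowest or highest specimen whose gap to its nearest neighbour was large for the group's range (Dixon's 95% value). Of 154 checks, on 51 genes, 24 list scores, the spike-in mean and the 3′ to 5′ ratio in 2 groups, 11 passed, and chance alone gives about 1 in 20.

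In HOSE 3, MECOM stood at 7.30 (log2 intensity) against 4.81 to 5.42 in the other HOSE, and PLEKHS1 at 6.35 against 4.68 to 4.94. MECOM was higher in all 3 tumour groups than in HOSE. PLEKHS1 was higher in LMP (5.85) and LGOSC (4.20), and did not pass in HGOSC (0.98, limma adjusted p = 0.334). ANKRD30BP3 in HOSE 5 was 13.41 against 12.95 to 13.11. The ovarian stroma and steroidogenic cell score of HOSE 5 was −0.16 against 0.98 to 1.64 in the others, and the macrophage and monocyte score of HOSE 1 was 2.11 against 0.03 to 0.78.

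Among LMP, RBM6 was 10.53 in LMP 1 against 5.64 to 7.68, TIMP3 was 7.87 in LMP 2 against 4.81 to 6.20, and MKI67 was 7.53 in LMP 4 against 6.41 to 6.77. RBM6 and TIMP3 were among the genes most raised in LGOSC over LMP. SERPINA5 was 8.91 in LMP 8 against 10.89 to 12.54. The interferon response score of LMP 3 was 0.36 against −0.96 to −0.42, and the homologous recombination score of LMP 6 was −1.03 against −0.64 to −0.32. No explanation was tested for these specimens.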

How the results depend on the processing

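Refits by array set, of the lists without 1 specimen, without some HOSE or HGOSC arrays, and on 1 side of the gap in LGOSC were chosen after the data were seen, and the other settings before. Under the planned settings AGR3 kept its direction and its side of the threshold in all 72 values, from −3.60 to −2.26 for HGOSC against LMP with LGOSC, −2.29 to −1.41 for HGOSC against LGOSC, −2.80 to −2.24 for LGOSC against LMP, 3.87 to 5.38 for LMP, 1.62 to 2.59 for LGOSC and 0.22 to 0.42 for HGOSC against HOSE. Not all 72 are separate checks, as AGR3 has 1 probe set. The filters, the mean of all probe sets and eBayes with a trend and robust variances cannot change its log2 difference. Fitting only the groups compared also leaves a pairwise difference unchanged. Under the added settings 13 AGR3 values kept direction and side of the threshold, 6 lost the call and 3 turned sign with no call in either fit. Gene counts stayed within 1.5 times in 70 of 84 planned refits and in 3 of 22 added ones. The weak signal of dim genes limits folds near the floor, and no paired analysis was possible because the labels do not tie specimens to patients. Except where fewer arrays or genes per fit account for it by construction, the cause was not tested.

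Leaving out 1 specimen gave 2736 to 3106 genes for HGOSC against LMP with LGOSC, 4059 to 4576 for HGOSC against LGOSC, 1778 to 2459 for LGOSC against LMP, and 3824 to 6299, 6823 to 8298 and 2215 to 4243 for LMP, LGOSC and HGOSC against HOSE. AGR3 then ranged over −3.09 to −2.79, −2.13 to −1.66, −2.86 to −2.40, 4.70 to 5.00, 1.95 to 2.42 and 0.15 to 0.47 in the same order.

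Among planned settings, the adjusted p alone as the threshold gave 9634, 10403, 4517, 11451 and 5206 genes (HGOSC against LMP with LGOSC, HGOSC against LGOSC, LGOSC against LMP, LGOSC against HOSE and HGOSC against HOSE), by construction a wider criterion. The mean of all probe sets gave 1663 genes for HGOSC against LMP with LGOSC, 2702 for HGOSC against LGOSC, 1253 for LGOSC against LMP, 3208 for LMP against HOSE and 1896 for HGOSC against HOSE, and put MKI67 at 0.0017 (LGOSC) and 0.70 (HGOSC) against HOSE. LGOSC against LMP gave 1315 genes with a pseudocount of 64 and 1107 with the 3′ to 5′ covariate. Array weights gave 8128 for LMP and 6222 for HGOSC against HOSE. In HGOSC against LMP with LGOSC, the T and NK cell call was lost with quantile normalisation (adjusted p = 0.0725), without _x_at and _s_at probe sets (0.0858), with the 3′ to 5′ covariate (0.0858) and with the fibroblast covariate (0.0666), at means of 0.43, 0.33, 0.22 and 0.33. There the fibroblast call was lost with the 75th percentile shift (0.0593), without those probe sets (0.157) and with its own score as covariate (0.728), at means of 0.92, 0.42 and 0.037, and the immediate early call without those probe sets (0.0736). In all, 37 list calls were lost under planned settings, 8 of them that of endoplasmic reticulum folding in HGOSC against HOSE (0.291 with quantile normalisation), and 3 each those of stroma in LGOSC and of replication and hypoxia in LMP against HOSE. With each specimen left out in turn, calls were lost in 13 of 28 refits for endoplasmic reticulum folding in HGOSC against HOSE (adjusted p up to 0.107), 9 of 21 for fibroblast genes in LGOSC against LMP (0.152), 8 of 43 for T and NK cell genes in HGOSC against LMP with LGOSC (0.0694) and 3 of 19 for ciliated cell genes in LGOSC against HOSE (0.0717). Against HOSE they were also lost in 2 of 28 each for macrophage (0.169) and mesenchymal genes (0.0824) in HGOSC, and 1 of 14 for replication in LMP (0.0513).

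The block by array set gave 804, 980, 723, 1023, 567 and 1210 genes (HGOSC against LMP with LGOSC, HGOSC against LGOSC, LGOSC against LMP, then LMP, LGOSC and HGOSC against HOSE), and the middle set alone 848, 243, 0 (351 at an unadjusted p under 0.05 in limma), 865, 435 and 1151. In HGOSC against LMP with LGOSC, both put ABI1 at −0.12, EGFR at −0.20, PCDHB9 at −0.036, CLNK at −0.0089, DYNLT2 at −0.30, AP3B2 at −0.19, ANKRD30BP3 at −0.12, SYCP3 at −0.085 and PAX8 at 0.045. The middle set gave AGR3 −2.82 and DYNLT2 −0.14 for HGOSC against LGOSC, and AGR3 −1.65, AGR2 0.59, the fibroblast mean −0.47 and the immediate early mean −0.63 for LGOSC against LMP. The high set gave 1248 genes and AGR3 −2.88 for LGOSC against LMP.

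Against HOSE, the block put MKI67 at 0.11 in LMP and at 0.37 in LGOSC, where AGR3 was 2.22 (adjusted p = 0.266), endoplasmic reticulum folding −0.52, EGFR 0.038, CLNK 0.13 and PCDHB9 0.35. In LGOSC the middle set gave AGR3 2.77, ABI1 0.032, EGFR 0.40, CLNK 0.51, PCDHB9 0.59 and MKI67 0.035, and in LMP endoplasmic reticulum folding −0.42 and MKI67 0.24. In HGOSC the block, the middle set and leaving out HOSE 1 to 4 each gave AGR3 −0.054, endoplasmic reticulum folding −0.20, MKI67 0.87 and ESR1 −0.082. These are 1 estimate, as each sets HGOSC against HOSE 5 and 6 alone.

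Without HOSE 1 to 4, 854, 2305 and 968 genes passed in LMP, LGOSC and HGOSC, AGR3 in LGOSC was 1.86, and MKI67 was 0.20 in LMP and 0.56 in LGOSC. Without HOSE 5 and 6, 7816 passed in LMP and 5952 in HGOSC. Without the 8 HGOSC arrays of narrow intensity range, 5053 passed in HGOSC against HOSE. The correlation of AGR3 with the ciliated cell score without the 2 farthest specimens was 0.45 in HOSE, −0.24 in LMP and 0.65 in LGOSC, with quantile normalisation 0.030 in HGOSC, and on the larger side of the gap in LGOSC 0.27.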

Other observations

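The bounds on AGR3 following the ciliated cell genes, the splits within array sets, the tests of array set as the whole cause of a difference, and the choice of genes within the middle set were made after the values had been seen. The other splits, the contrast of array sets, the 3′ to 5′ covariate and the tests behind the LGOSC relation were fixed before their results.

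Applied within the middle set alone, the rule for named genes gave another set of genes raised in HGOSC over LMP and LGOSC. Besides IFI6 (3.41) and CXCL10 (3.02), they were the cell division genes FAM83D (3.27), CEP55 (3.15) and MELK (2.88), the matrix and Wnt-related genes CTHRC1 (3.12), SFRP2 (3.02), LUM (2.88) and TIMP3 (2.86), and MAL (2.93). The 10 lower genes were SPATA18 (−4.88), CIMIP1 (−4.64), CFAP43 (−4.61), FAM81B (−4.46), CFAP52 (−4.14), CFAP126 (−4.05), AGR3 (−4.00), PLEKHS1 (−3.96), SPMIP6 (−3.84) and FYB2 (−3.83). AGR3 was thus among the 10 lowest genes in this set and not over all arrays. The pooled group there held 5 LMP and 2 LGOSC, against 8 and 13 over all arrays. Mean AGR3 was 10.45 in LMP and 7.83 in LGOSC. This change of mix would by itself make the AGR3 difference larger, so the rank does not separate it from array set.

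The first pattern is the count of 2881 genes between HGOSC and LMP with LGOSC. High against middle set at fixed tumour group, within LMP and LGOSC, gave 1653 genes, so array set may account for part of the count. Of these, 978 were among the 2881, and 975 of the 978 had the sign that array set would give them. The same LMP and LGOSC arrays enter both contrasts, 14 of them in the high set. This agreement in sign is thus partly built in and adds no separate support. Within the middle set the ciliated cell genes (−2.28), the mitosis genes (1.83) and AGR3 (−4.00) still differed. This argues against array set as the whole cause there, by bounds set after the values were seen. The pooled group of that set is 5 LMP and 2 LGOSC, so this does not extend to LGOSC alone. Against its 2 LGOSC, AGR3 stood at −2.82 and did not pass (limma adjusted p = 0.0789). Spike-in means within the set were 11.11 in HGOSC, 11.47 in LMP and 11.65 in LGOSC. AGR3 stood at −3.60 with the 3′ to 5′ ratio as a covariate, which argues against RNA quality, as far as that ratio reads it, as the whole cause. Tumour grade stays open as the biological explanation for the ciliated, mitosis and AGR3 differences, as a hypothesis. The lists and genes lost within the set cannot be assigned.

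The second pattern is the 10 genes of largest HGOSC excess, from ZBTB33 to SYCP3. Their median difference between the high and the middle set at fixed group was −5.64, and within the middle set HGOSC and LMP with LGOSC differed by a median of −0.10. These values fit array set in place of tumour group, so those 10 differences may be technical. What made the array sets differ was not tested.

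The third pattern, that AGR3 follows ciliated cell genes between specimens of 1 group, was a hypothesis set before the data were examined. It stays open in HGOSC (r −0.014, upper 95% bound 0.41), where mean AGR3 lay below every array's median. The ciliated cell genes of HGOSC did not differ from HOSE as a list and so may give little signal to follow. It also stays open in HOSE (r −0.12, n = 6) and LMP (r 0.31, n = 8), where the specimens are too few. The bound on r alone would exclude it in HGOSC, and the condition that the list differ from HOSE was added after that value was known. In LGOSC r was 0.76 (adjusted permutation p = 0.00976), which fits. It was 0.70 within the high set (n = 11, 95% interval 0.18 to 0.92) and 0.78 with the 3′ to 5′ ratio regressed out. These values argue against array set and RNA quality as its source. They do not exclude them, as the interval is wide and the ratio reads RNA quality from ACTB and GAPDH alone. Of 17536 genes outside the list, 1.49% had r as high there (AGR3 was number 262). That share lies between the bounds set beforehand, so the test cannot tell whether AGR3 stands apart from genes in general. The genes outside the list also include others of the cilium, such as CFAP43. Without the 2 farthest specimens r was 0.65 (adjusted permutation p = 0.104). A further condition, that r be as high in the 10 specimens below a gap in the score, had kept it open and was dropped after the values were known. The ground was the narrower range, which lowers r only if 1 linear relation holds throughout. The r of 0.27 there leaves open that the 3 specimens above the gap carry the relation. A shared differentiation state of a few specimens may give the same values and was not tested.

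Chance division of the specimens was tested with 100 splits per comparison, the real one included, and could be excluded in all 6, with 1 split of 100, the real one, giving as many genes. These splits exchange specimens across the array sets, so they do not separate group from array set. The real count and the highest of the others were 2881 and 264 for HGOSC against LMP with LGOSC, 4176 and 456 for HGOSC against LGOSC, and 2026 and 627 for LGOSC against LMP. For HGOSC against HOSE they were 2902 and 1663, the second from a split that set HOSE 1 to 3 with HGOSC 5, 8 and 16 against the rest, in part along the array sets, and the blocked count was 1210. For LMP against HOSE they were 5031 and 4848, the second from a split that set HOSE 5 and 6 with LMP 1, 3, 7 and 8 against the rest, in part along the array sets, and the blocked count was 1023. For LGOSC against HOSE they were 7474 and 5465, the second from HOSE 1 to 4 with LGOSC 11 and 12 against the rest, in part along the array sets (HOSE 1 to 4 are the low set, LGOSC 11 and 12 are in the high set), and the blocked count was 567. Splits that exchanged specimens only inside an array set, counted with the block, gave fewer genes than the real one in each comparison. The real count and the highest other were 804 and 429 (HGOSC against LMP with LGOSC), 980 and 391 (HGOSC against LGOSC), 723 and 136 (LGOSC against LMP) and 1210 and 253 (HGOSC against HOSE) over 100 splits each, and 1023 and 105 over all 21 for LMP against HOSE. For LGOSC against HOSE they were 567 and 2, but 6 splits are too few for a share under 0.05.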
